A study of Mus musculus with 6 samples.

How the data were processed

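Liver RNA was measured by RNA sequencing in 6 libraries from LiKM mice, 3 labelled AFP-positive and 3 labelled AFP-negative. Per the labels, the mice carry a mutant Kras allele and lack Mdm2 in the liver, and the tissue was fixed in formalin, embedded in paraffin and collected by laser microdissection at 4 months of age. AFP is alpha-fetoprotein, a protein of fetal liver that many liver tumours make again, and it defines the regions. Libraries were made, per the labels' protocols, with a SMARTer stranded kit for very small amounts of total RNA and sequenced as pairs of 101 bp reads on a NovaSeq instrument.

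The deposited file holds estimated counts per gene symbol for 24421 genes, not scaled for depth. Between 22.5% and 27.1% of the genes in a library have a value that is not a whole number (further than 1e-06 from one). How the fractions arose is not stated. Over the gene families used for the background estimate, a non-whole value in any library was found for 40.5% of genes that share a stretch of 31 bases with a GENCODE M21 transcript of another gene and for 1% of genes that do not. Cuffdiff 2.2.1 is named in the submitters' processing notes. The aligner, the genome build, the annotation and whether counting used the strand are not given in the sources used here, so no coordinates are printed and overlapping genes on opposite strands cannot be told apart. Genes of the mitochondrial genome have no row, and the list of mitochondrial transcripts had 0 measured members. Total counts ran from 6974668 to 14130145 per library. The rows of Rn45s and Lars2, which carry ribosomal RNA sequence or a stretch resembling it, held 17.2% to 26.8% of the counts of a library.

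Groups came from the sample titles. The titles also give one number to an AFP-positive and an AFP-negative library in each of 3 pairs (numbers 50, 262 and 839). The number was read as marking regions of one mouse and kept as a block, a choice made with the other main choices before the data were examined; no label states it outright. The counts do not show the pairing on their own. The correlation of the deviations of same-numbered libraries from their group means was 0.165, -0.119 and -0.146 in pairs 1, 2 and 3, and 2 of 6 libraries correlated best with their own number. Without the block the gene test called 0 genes. No label says which libraries come from separate animals, so p-values cannot be read as measuring the spread between animals. With the block, edgeR set the prior degrees of freedom to infinity (23.2 without it), so each gene's spread was replaced by the trend over all genes. The edgeR SE and p-values with the block therefore do not measure a gene's own spread between pairs. Libraries of one group differed from each other by far more than counting noise (chi-square per degree of freedom of at least 22.1).

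Counts were rounded to whole numbers, filtered with filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood F-test of edgeR 4.0.16 with the block, under R 4.3.3, leaving 2 residual degrees of freedom per gene before moderation. A gene was called at a Benjamini-Hochberg false discovery rate (FDR) under 0.05 over 21902 genes. Fold changes are AFP-positive over AFP-negative on the log2 scale, and their standard errors (SE) were taken as the size of the log2 fold change divided by the square root of F. Values per library are TMM-scaled CPM (counts scaled to a common library size). Of 30 gene lists fixed beforehand, 29 had measured members and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with adjustment over the lists. The correlation estimated per list and fry were alternatives. Of 692 listed members, 674 had a row.

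Named genes follow a rule set in advance. It takes Afp, Mdm2, Kras and Trp53 whatever their values; called genes with one sign in all 3 pairs and a mean log2 CPM of at least 2, up to 12 in each direction; up to 4 members of each list with the smallest p; and Xist with the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d. Genes named outside it are marked as chosen after their values were seen.

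Background was estimated after the data were seen. Olfactory, vomeronasal and taste receptor genes, keratin-associated protein genes and beta-defensin genes are not used by liver cells, and the median count per coding kilobase over 1502 of them (coding length of at least 500 bp) gave a background density per library. Multiplied by exonic length, it gave an expected background per gene. Lengths were taken by symbol from GENCODE M21, for 95.7% of the genes in the file; the authors' annotation may differ.

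Alternatives were other scalings (DESeq2's size factors, upper quartile, library size without the 20 most abundant genes), no filter or a filter at a mean log2 CPM of 2, DESeq2 1.42.0, limma voom with and without quality weights, no block, a test against a fold change of 1.5, and leaving out each pair or library. Added after the data were seen were subtraction of the expected background, the background density as a covariate, and keeping only genes above 3 times the background.

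The test was checked on counts simulated for AFP-positive against AFP-negative over 20937 genes, with the means, library sizes and dispersion of the real libraries. With the block it recovered 5.97% of genes changed 2-fold, 44.8% of those changed 4-fold and 72.7% of those changed 8-fold, with 5 false calls. A list of genes lowered by 0.7 on the log2 scale was found by camera, with 0 other lists called of 29. Genes were drawn independently there, whereas correlations estimated in the real lists ran up to 0.982. The simulation therefore cannot tell how many of the real list calls are false.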

Results

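The data are RNA sequencing counts from 6 libraries of laser-microdissected liver of LiKM mice, 3 labelled AFP-positive and 3 labelled AFP-negative, in 3 pairs that share a number. The comparison asks how liver tissue labelled positive for alpha-fetoprotein differs from tissue labelled negative. Total counts were 8165594, 12272937 and 11295212 in the libraries labelled AFP-negative 1, 2 and 3, and 6974668, 9327138 and 14130145 in those labelled AFP-positive 1, 2 and 3.

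Afp, the gene whose protein was used to choose the regions, is no finding between them and serves to check the labels. It was measured at 167 and 321 CPM in the libraries labelled AFP-positive 1 and 2, against 15.4 and 25.5 CPM in those labelled AFP-negative 1 and 2. In the third pair it went against the labels, with 29.6 CPM in the library labelled AFP-positive 3 and 61.4 CPM in the library labelled AFP-negative 3. The log2 difference was 3.42, 3.65 and -1.04 in pairs 1, 2 and 3, and over all libraries the log2 fold change was 2.26 (SE 0.59, edgeR FDR 0.504). Whether Afp is called depends on the setting: without pair 3 its FDR was 7.16e-09, and over all pairs, at log2 fold changes of 1.95 to 2.3, it was 0.00322 with upper-quartile scaling, 0.0296 at a mean log2 CPM of at least 2 and 0.00414 with limma voom, against 1 with DESeq2. Every direction below is drawn between libraries as labelled, and pair 3 is given beside a called list where its sign differs.

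Gpc3, which encodes glypican-3, a cell-surface proteoglycan of fetal liver and of liver tumours, rose in the libraries labelled AFP-positive. It was measured at 52.9 ± 16.2 CPM (SD, n = 3) there and at 11.4 ± 7.26 CPM (SD, n = 3) in the libraries labelled AFP-negative. The log2 fold change was 2.33 (SE 0.40), higher in 3 of 3 pairs by 2.54, 2.98 and 1.44, the third pair included although Afp runs the other way there. It was the single gene of 21902 called (edgeR with the block, FDR 0.000182), with 0 genes that fell. Without the block, the fit that left out the library AFP-positive 1 called Gpc3 (FDR 0.0187). Over all libraries without the block, however, the call was lost, with an FDR of 0.287 and 0 genes called. It was also lost without pair 1 or pair 2 (FDR 1 in each) and after subtraction of the expected background (log2 fold change 2.79, FDR 0.51). Unadjusted p was under 0.05 for 344 genes with the block, of which 206 were higher and 138 lower, where chance alone gives 1095. Without pair 3 the edgeR test called 256 genes, 18 higher and 238 lower. Of these, only 7 of the higher and 231 of the lower genes were over 3 times background. The other higher genes included the olfactory receptor genes Olfr114 and Olfr937, named after their values were seen, of a family used to estimate background. DESeq2 on all pairs called 5 genes, of which Gpc3 and Gldn were higher and Cyp7b1, Mup21 and Mup7 lower. Apart from Gpc3 and Cyp7b1, the genes that DESeq2 called were chosen after their values were seen.

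**Figure D1:**
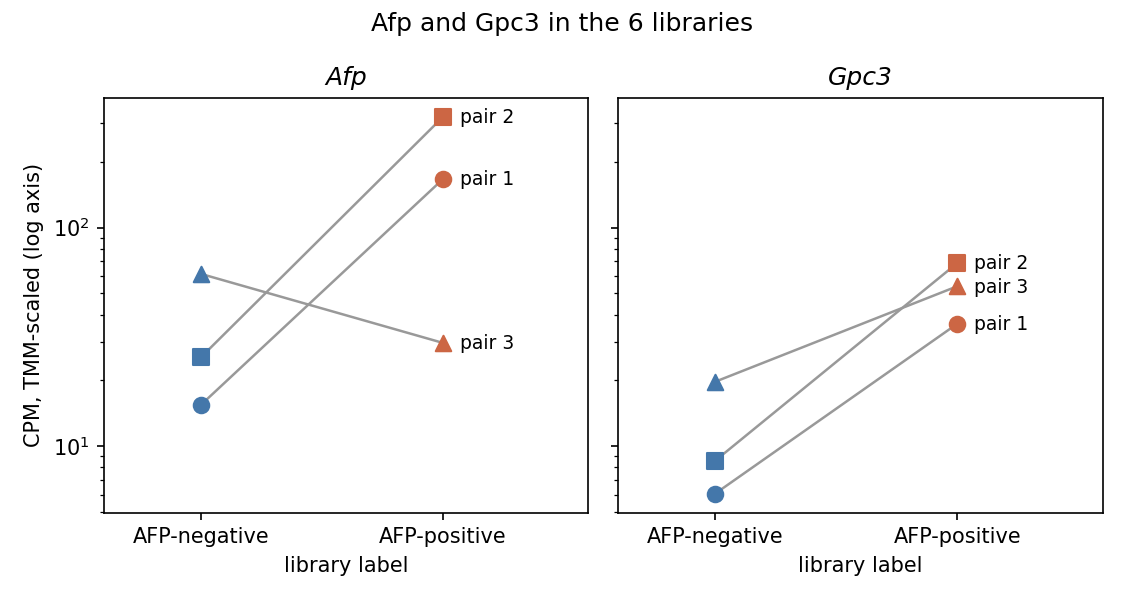
Afp and Gpc3 in the 6 libraries, as TMM-scaled CPM on a log axis; blue points are libraries labelled AFP-negative, orange points those labelled AFP-positive, and lines join libraries with the same number. Afp falls from 61.4 to 29.6 CPM in pair 3 and rises in the other pairs, whereas Gpc3 is higher in the library labelled AFP-positive in 3 of 3 pairs.

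The genes engineered in these mice, Mdm2 and Kras, were not called between the regions, and neither was Trp53. Mdm2, which encodes the ubiquitin ligase that degrades p53, differed by a log2 fold change of 0.09 (SE 0.38, edgeR FDR 1), Kras by -0.04 (SE 0.38, edgeR FDR 1) and Trp53, the gene of p53, by 0.12 (SE 0.43, edgeR FDR 1). Mdm2 was measured at 29.8, 27.8 and 40.0 CPM in the libraries labelled AFP-negative 1, 2 and 3 and at 34.8, 19.6 and 58.2 CPM in those labelled AFP-positive 1, 2 and 3. Counts per gene do not tell a recombined allele from an intact one. Among 34 p53 target genes 0 were called, also adjusted over the list alone, and the list was not called (median log2 fold change -0.05, camera FDR 0.756).

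Genes of drug metabolism and bile acid synthesis, functions of mature hepatocytes, were lower in the libraries labelled AFP-positive as groups. The cytochrome P450 list fell (median log2 fold change -0.69, 31 of 34 members lower, camera FDR 3.48e-11), as did bile acid synthesis and transport (-0.50, 18 of 20 lower, FDR 6e-06). With an estimated correlation neither call held (adjusted p = 0.968 for both). Of their members, 0 were called over all genes; adjusted over the list alone 3 P450 genes fell (Cyp4a10, Cyp2c54 and Cyp2c37) and 1 bile acid gene fell (Cyp7b1). Cyp7b1, an oxysterol hydroxylase, was at 25.2 ± 12.8 against 79.4 ± 27.9 CPM (SD, n = 3 each) and lower in 3 of 3 pairs, with a log2 fold change of -1.74 (SE 0.42). Its edgeR FDR was 0.414, and 0.0307 with DESeq2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.89 (SE 0.39, edgeR FDR 1). The P450 list's median was -0.81 and -1.49 in pairs 1 and 2 and 0.21 in pair 3, and the bile acid list's was -0.78, -1.21 and 0.34. After subtraction of the expected background the falls in pairs 1 and 2 were smaller, at -0.55 and -1.17 for the P450 list and -0.635 and -0.92 for the bile acid list. Pair 3 moved to -0.18 for the P450 list and -0.05 for the bile acid list. Both calls were lost without pair 2 (camera FDR 0.247 and 0.332). The Cyp2c and Cyp4a genes have near-identical copies, so their single values are uncertain.

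The list of Wnt and pericentral genes, which mark hepatocytes around the central vein, also fell (median log2 fold change -0.46, 16 of 22 members lower, camera FDR 8.12e-05; adjusted p = 0.968 with an estimated correlation). Its median was below 0 in each pair, at -0.79, -0.88 and -0.16, also after subtraction of the expected background (-0.80, -0.63 and -0.45). Over all genes 0 members were called, and adjusted over the list alone 1 fell, Rhbg, an ammonium transporter (3.94 ± 1.88 against 12.9 ± 2.87 CPM, SD, n = 3 each). Oat, a pericentral enzyme of ornithine breakdown, was lower in 3 of 3 pairs (log2 fold change -1.38, SE 0.51, edgeR FDR 1). Slc1a2, a glutamate transporter of the same zone, had -1.12 (SE 0.48, edgeR FDR 1), lower in 3 of 3 pairs, and Cyp1a2 -1.14 (SE 0.54, edgeR FDR 1). The call was lost without pair 2 (FDR 0.129). Cyp1a2, Cyp27a1, Oat and some other members also belong to other lists that fell, so these lists are not separate evidence.

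Amino acid breakdown, fat oxidation, acute phase and antioxidant genes fell as lists in the same direction, each with its sign turned in pair 3. The urea cycle and amino acid breakdown list had a median log2 fold change of -0.36 (29 of 30 lower, camera FDR 0.000186), with a median of 0.67 in pair 3. Fatty acid oxidation and ketogenesis had -0.51 (24 of 25 lower, FDR 8.12e-05), with 0.44 in pair 3. The acute phase list had -0.29 (16 of 22 lower, FDR 0.00223), with 0.17 in pair 3, and NRF2 targets and glutathione had -0.37 (18 of 22 lower, FDR 0.00223), with 0.23 in pair 3. After subtraction of the expected background the falls in pairs 1 and 2 were smaller. The urea cycle medians moved from -0.60 and -1.14 to -0.26 and -0.76, those of fatty acid oxidation from -0.67 and -0.96 to -0.39 and -0.61, and those of the acute phase list from -0.51 and -0.74 to -0.19 and -0.47, and the acute phase call was lost (FDR 0.0676). The pair 3 medians of the acute phase and NRF2 lists were then -0.03 and -0.13, and those of the urea cycle and fatty acid lists 0.30 and 0.06. Plasma protein genes moved in the same pattern, at -0.51, -0.61 and 1.02 in pairs 1, 2 and 3. Less their median, the acute phase list was at 0.002, -0.13 and -0.85, NRF2 targets at -0.11, -0.10 and -0.79, the urea cycle list at -0.08, -0.53 and -0.35 and fatty acid oxidation at -0.15, -0.35 and -0.58. None of the 4 calls held with an estimated correlation (adjusted p = 0.968 for each). In these 4 lists 0 members were called over all genes; adjusted over the list alone 3 acute phase genes fell (Saa2, Saa1 and Orm2) and 0 members of the other lists. Saa1 was at 11.6 ± 7.63 against 31.5 ± 19.4 CPM (SD, n = 3 each) and lower in 3 of 3 pairs, but Saa1 and Saa2 are near-identical, so how their fragments were divided is uncertain. Without pair 1 or without pair 2 each of these 4 calls was lost, and the urea cycle list then turned upwards without pair 2 (FDR 0.74).

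**Figure D2:**
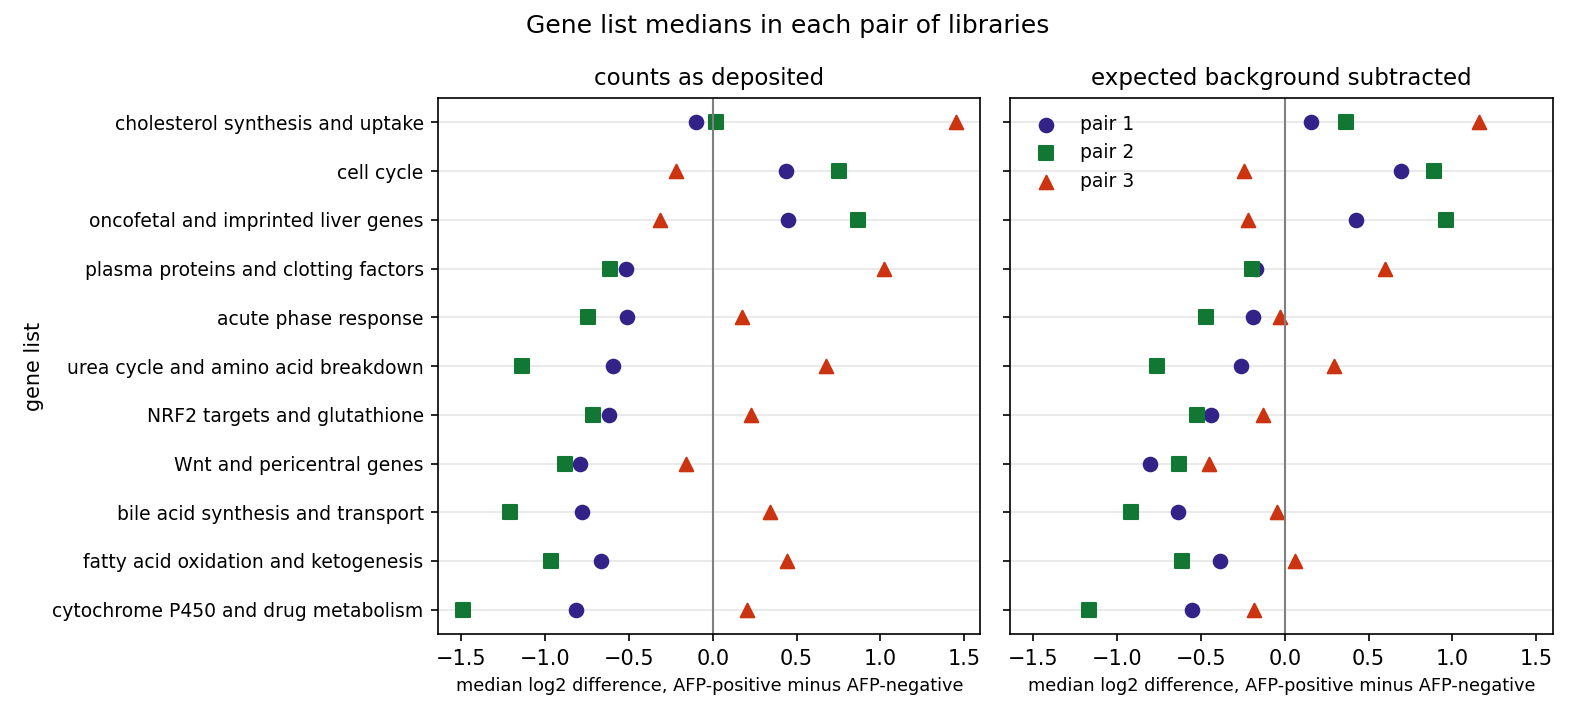
Median log2 difference (AFP-positive minus AFP-negative) of the members of the 10 called gene lists and of the plasma protein list, in pairs 1 (circles), 2 (squares) and 3 (triangles), on the counts as deposited (left) and after subtraction of the expected background (right). In the left panel, Wnt and pericentral genes are below 0 in all 3 pairs, and the plasma protein list goes from -0.51 and -0.61 in pairs 1 and 2 to 1.02 in pair 3.

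Cholesterol synthesis and cell cycle genes rose as lists, and the oncofetal list was called with Afp among its members but not without it. Cholesterol synthesis and uptake had a median log2 fold change of 0.43 (21 of 23 members higher, camera FDR 0.00292), with its highest median in pair 3: the medians were -0.10, 0.02 and 1.45, and 0.16, 0.37 and 1.16 after subtraction of the expected background (camera FDR 1.87e-05). Mvk, which encodes mevalonate kinase, was higher in 3 of 3 pairs (log2 fold change 1.11, SE 0.38, edgeR FDR 1), and Hmgcr, the rate-limiting enzyme, had 0.72 (SE 0.53, edgeR FDR 1). Less the plasma protein median, which was 1.02 in pair 3, the list's medians were 0.42, 0.64 and 0.43. Without pair 3 the call was lost and the list pointed downwards (FDR 0.227). It pointed upwards there after subtraction of the expected background (FDR 0.225). The cell cycle list had 0.39 (29 of 36 higher, camera FDR 0.00431), with medians of 0.44, 0.75 and -0.22. Among genes over 3 times background its medians were 0.78, 1.04 and -0.60. Some lists of other cell types moved in the same pattern there, among them T, NK and B cell markers (8 members left) at 0.39, 1.39 and -0.72 and stellate genes at 0.43, 0.71 and -0.47. Macrophage markers, at 0.05, -0.07 and -0.20, and endothelial markers, at -0.25, -0.004 and 0.16, did not. Kif20a, a kinesin of cell division, was higher in 3 of 3 pairs (1.02, SE 0.51, edgeR FDR 1), although the expected background came to 45.0% of its counts, and Top2a was higher in pairs 1 and 2 only (0.64, SE 0.41, edgeR FDR 1). The oncofetal list had 0.34 (15 of 20 higher, camera FDR 0.0202), with medians of 0.45, 0.87 and -0.32, and a camera FDR of 0.0528 without Afp, a setting chosen after the data were seen. Over all genes 1 of its members rose, Gpc3; adjusted over the list alone 2 rose, Gpc3 and Afp, the latter being the gene that chose the regions. Of the cell cycle and cholesterol members 0 were called either way. With an estimated correlation none of these 3 calls held (adjusted p = 0.968 for each), and the cell cycle and oncofetal calls were lost without pair 1 or without pair 2 (FDR 0.0623 to 0.402). Subtraction of the expected background also ended the oncofetal call (FDR 0.0676), although its pair medians over the 18 members left were close to those before, at 0.43, 0.96 and -0.22.

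Other hepatocyte lists were not called over the 3 pairs, and several of them had opposite signs in pairs 1 and 2 and in pair 3. Plasma protein and clotting factor genes, the most abundant products of hepatocytes, had a median log2 fold change of -0.06 (29 of 45 lower, camera FDR 0.686), with -0.51, -0.61 and 1.02 in pairs 1, 2 and 3. Lipogenesis had 0.28 (FDR 0.607), with -0.24, -0.40 and 1.37 in the pairs, gluconeogenesis and glycogen -0.27 (FDR 0.0528), with 0.75 in pair 3, the unfolded protein and stress response -0.19 (FDR 0.0531), with 0.21 in pair 3, and hepatocyte transcription factors -0.12 (FDR 0.145), with 0.60 in pair 3. Without pair 3, whose Afp goes against its labels, camera called each of these 5 lists lower: plasma proteins (FDR 3.2e-09), lipogenesis (FDR 0.000983), gluconeogenesis (FDR 3.21e-07), the unfolded protein response (FDR 0.00321) and transcription factors (FDR 0.000184). After subtraction of the expected background, again without pair 3, of these 5 only gluconeogenesis was called (FDR 0.00653), against 0.157 for plasma proteins, 0.711 for lipogenesis, 0.591 for the unfolded protein response and 0.0618 for transcription factors. The medians of plasma proteins in pairs 1 and 2 were then -0.17 and -0.20, and those of lipogenesis 0.08 and -0.03. With an estimated correlation none of the 5 was called without pair 3 (adjusted p = 0.514 to 0.536). Without pair 2 camera called plasma proteins (FDR 0.0111) and lipogenesis (FDR 0.00489) higher at the preset correlation, and with a background covariate lipogenesis was called higher too (FDR 0.00394). Glycolysis of growing cells had -0.03 (FDR 0.999), with 0.62 in pair 3, the ERK pathway's output genes 0.07 (FDR 0.952), with -0.33 in pair 1, and YAP and TAZ targets -0.03 (FDR 0.145), with 0.04, 0.19 and -0.19 in the pairs. The camera direction of the ERK list was down, against the sign of its median. The senescence-associated secretory factors had 0.03 (FDR 0.607), with -0.48 in pair 3, and again a camera direction down and a mean of -0.10. The mean of the glycolysis list was 0.04, against the sign of its median. In these lists 0 members were called, also adjusted over the list alone.

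Lists of markers of other cell types were not called over all tested genes and all 3 pairs. Without pair 3, camera called neutrophil markers higher (FDR 0.0268) and red cell transcripts (FDR 0.0093) and interferon and MHC class I genes (FDR 0.0465) lower. None of these 3 held after subtraction of the expected background (FDR 0.242, 0.166 and 0.792) or with an estimated correlation (adjusted p = 0.514 for each). Progenitor and cholangiocyte markers had a median log2 fold change of 0.11 (camera direction down, FDR 0.999), stellate cell and matrix genes -0.06 (FDR 0.952), macrophage and Kupffer cell markers -0.10 (FDR 0.34) and endothelial markers -0.06 (FDR 0.952). The stellate list had -0.34 in pair 3 and 0.24 and 0.31 in pairs 1 and 2, and the endothelial list 0.46 in pair 3. T, NK and B cell markers had 0.28 (FDR 0.281, and 0.0459 upwards among genes over 3 times background, a setting chosen after the data were seen), with -0.42 in pair 3. Of the rest, neutrophil markers had 0.04 (FDR 0.61), with -0.66 in pair 3, red cell transcripts -0.27 (FDR 0.276), with 0.76 in pair 3, interferon and MHC class I genes -0.02 (FDR 0.625), with 0.26 in pair 3, and nuclear-retained long RNAs 0.10 (FDR 0.952). The means of the stellate and endothelial lists were 0.0024 and 0.02, against the sign of their medians. Of their members 0 were called, also adjusted over the list alone. Many of these genes lay near the background. It made up 39.9% of the counts of the T, NK and B cell list, 30.5% for progenitor and 17.9% for stellate genes. Whether small differences could be detected in these lists was not tested. Stellate members went both ways, with Lrat, a retinol-esterifying enzyme, at a log2 fold change of -1.01 (SE 0.40) and lower in 3 of 3 pairs, Thy1 at -1.29 (SE 0.71) and the collagen genes Col1a1 at 0.85 (SE 0.39) and Col1a2 at 0.78 (SE 0.38), each with an edgeR FDR of 1.

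Libraries differed in background. The median count over gene families not used by liver was 1.05, 0.426 and 1.43 CPM per coding kilobase in the libraries labelled AFP-negative 1, 2 and 3, and 1.98, 1.49 and 0.443 in those labelled AFP-positive 1, 2 and 3. It was thus higher in the library labelled AFP-positive in pairs 1 and 2 and lower in pair 3, the pattern also seen in Afp. The expected background came to between 3.2% and 14.8% of the counts of a library, and 51.3% of the tested genes had summed counts under 3 times their expected background. Y-linked Ddx3y was counted in each library (37.4 to 80.0 CPM). The expected background came to 222% of the counts of Xist, so these genes do not tell the pairs apart. For Xist the estimate was thus too high, and values after its subtraction are approximate.

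**Figure D3:**
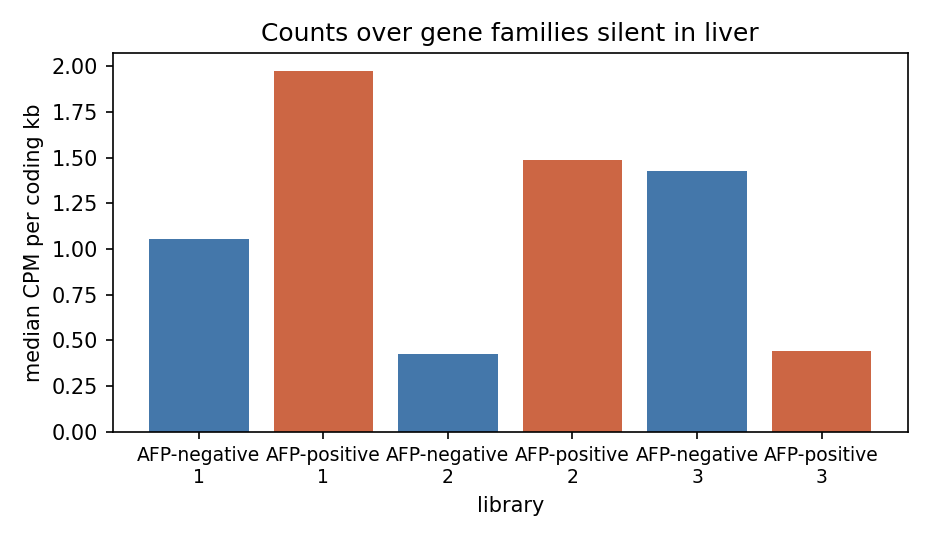
Background density per library, as the median CPM per coding kilobase over 1502 receptor, keratin-associated protein and beta-defensin genes; bars are single libraries, blue for those labelled AFP-negative and orange for those labelled AFP-positive. The values run from 0.426 to 1.98, and pair 3 is ordered opposite to pairs 1 and 2.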

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

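The background settings, the lists without Afp and the settings that join these or an estimated correlation to leaving out pair 3 were chosen after the data were seen. The count of called genes, 1 with edgeR and the block, was also 1 with DESeq2's size factors, no filter or a fold change above 1.5. It was 5 with upper-quartile scaling, 35 with the library size taken without the 20 most abundant genes, 5 at a mean log2 CPM of at least 2, 5 with DESeq2, 4 with limma voom and 8 with its quality weights. It was 0 with no replicate block, 0 after background subtraction with or without the block, 93 with the background covariate and 14 among genes over 3 times background. Leaving out a pair gave 0 without pair 1 or pair 2 and 256 without pair 3. Of the 256, 7 higher and 231 lower genes were over 3 times background. Leaving out single libraries, without the block, gave 0 or 1. The causes of these differences were not tested. Gpc3 was higher in the libraries labelled AFP-positive in each of these fits, with a log2 fold change of 1.9 to 2.85 and an FDR from 3.5e-12 to 1. Afp, not called in the main fit (FDR 0.504), was called with upper-quartile scaling (0.00322), without the 20 most abundant genes (2.45e-10), at a mean log2 CPM of at least 2 (0.0296), with limma voom (0.00414) and its quality weights (1.59e-12), the covariate (6.77e-11), genes over 3 times background (0.00724) and without pair 3 (7.16e-09).

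The count of called gene lists, 10 at the preset correlation, was also 10 with DESeq2's size factors, no filter or no replicate block, the same 10 lists each time; the block changed no call of a list. It was 8 after background subtraction (the oncofetal and acute phase lists were lost, FDR 0.0676 each), 11 with the covariate, 11 among genes over 3 times background and 9 without Afp (the oncofetal list was lost, FDR 0.0528). It was 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.976); the estimates ran up to 0.982. Leaving out pairs gave 3 to 17 lists, and leaving out pair 3 gave 9 after background subtraction and 0 with an estimated correlation. Without pair 2, 1 of the 10 was kept, cholesterol synthesis; without pair 1, 4; without pair 3, 9. Turned in direction were the urea cycle list (FDR 1.67e-11 to 0.74 over the pairs left out, upwards without pair 2), plasma proteins (3.2e-09 to 0.288, upwards at 0.0111 without pair 2), lipogenesis (0.000983 to 0.12, downwards at 0.000983 without pair 3) and cholesterol synthesis (0.000156 to 0.227, downwards without pair 3, and downwards at 0.639 there with an estimated correlation). After background subtraction, cholesterol synthesis pointed upwards without pair 3 (camera FDR 0.225). The cause of these turns was not tested. A further 55 gene values and 53 list values changed sign with no call on either side. The self-test with the block recovered 5.97% of genes changed 2-fold, and 0 of the 7 among them at a mean log2 CPM of 5 or more. Changes of that size are thus mostly below what these 6 libraries can call, also for well-counted genes.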

Other observations

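The tests of background against Afp, of a label swap after background subtraction, of the length dependence and of the P450 list were chosen after the result was seen, as was the male-biased gene list. Among the genes with the lowest p were several that male mouse liver makes more than female liver. A list of male-biased liver genes was written after Mup21, Cyp7b1, Elovl3 and Cyp4a12b had been seen. Over its other 19 tested members, 17 were lower in the libraries labelled AFP-positive, with a median log2 fold change of -0.73 (camera p = 1.39e-08 at the preset correlation; adjusted p = 2.78e-08, and adjusted p = 0.37 with an estimated correlation). The median was -0.69, -1.38 and -0.08 in pairs 1, 2 and 3, and -0.64, -1.26 and -0.45 after background subtraction. Less the plasma protein median it was -0.17, -0.77 and -1.09, and -0.47, -1.07 and -1.05 after background subtraction. On the counts as deposited, most of the fall in pair 1 was thus shared with plasma protein genes. Mup7, which DESeq2 had called, and members of the other lists were then left out too. Of the 15 left, 13 were lower, with a median of -0.49 (camera adjusted p = 1.4e-05, and adjusted p = 0.37 with an estimated correlation). Less the plasma protein median, these 15 were at -0.04 in pair 1, and at -0.35 there after background subtraction. Female-biased genes had a median of 0.32 and did not fall (camera adjusted p = 0.306), with 0.14, 0.70 and -0.17 in the pairs. They are a weak control: Ddx3y was counted in each library, and genes that male liver makes less of may have had little room to fall. A lower male-biased liver program in AFP-positive tissue is a hypothesis only. Several members of the male-biased list are Mup genes whose near-identical copies share fragments, and the estimated correlation leaves no call.

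Keeping only the 10217 genes over 3 times background, edgeR with the block called 14 genes, chosen here after their values were seen. Higher in the libraries labelled AFP-positive were Gpc3, Gldn, Afp, Tff3, Akr1c18, Col4a3, Sgsm1, B4galt6 and Abcd2, and lower were Cyp7b1, Mup21, Elovl3, Saa1 and Oat. Gldn, which encodes the adhesion protein gliomedin, was higher in 3 of 3 pairs (log2 fold change 1.67, FDR 7.73e-05 in that fit and 0.441 over all genes). Tff3, a secreted trefoil peptide, had 1.43 (FDR 0.0124 in that fit and 1 over all genes).

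Afp was lower in the library labelled AFP-positive 3 than in that labelled AFP-negative 3. Background reads do not account for it: of 826 Afp counts in AFP-negative 3, 33.3 were expected from background, and the ratio of AFP-negative 3 to AFP-positive 3 was 2.06 after subtraction and 2.07 before. Swapped labels in the third pair stay open: for genes called from pairs 1 and 2 and over 3 times background, without Afp, the median pair 3 difference of the 6 that rose minus that of the 231 that fell was -0.397, within the 95% range of matched random sets (-0.587 to 0.137); with Afp, which was left out only after this value was seen because it is the pattern itself, it was -1.02, outside the range, while Gpc3 followed the labels by 1.44. After background subtraction, of 97 other genes higher in pairs 1 and 2 at an unadjusted p under 0.01, 16 were higher in pair 3 (median -0.93), as a swap would give. But of 203 that were lower, 100 were lower in pair 3 (median 0.01), where a swap would turn them upwards. The background was also higher in the AFP-positive library in pairs 1 and 2 and lower in pair 3. The turn of the 97 genes therefore cannot tell a swap from background left after subtraction. AFP-positive tissue carried into the AFP-negative 3 region also stays open, since over 8 other oncofetal genes the median difference from AFP-negative 1 and 2 was 0.157, with Gpc3 (1.51), H19, Mest, Igf2bp3 and Ly6d higher there and Scd2, Tspan8 and Cpe lower (range of random sets -0.309 to 0.435), as does a true difference between the tissues sampled.

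Genes silent in liver held counts in every library. Fragments shared between their paralogs do not account for this, because 100 of them with no stretch of 31 bases in a GENCODE M21 transcript of another gene had 1.09 times the median count per kilobase of the other 1402, and genes with whole-number counts in all 6 libraries had 0.929 times that of the others. A background spread over the genome by length, such as from DNA or unspliced RNA in fixed tissue, stays possible. Counts followed coding length only loosely (Spearman 0.299 over 1502 genes, which are not independent replicates). Between libraries the median of 1471 receptor genes varied by 4.63 times. That of 95 unrelated keratin-associated and defensin genes, of any coding length, varied by 7.87 times. Both classes were higher in the AFP-positive library in pairs 1 and 2 and lower in pair 3. Their highest library differed, AFP-positive 1 for receptors and AFP-negative 3 for the others. The estimate is rough: expected background came to 222% of the counts of Xist and 120.5% of those of Krt7. No biological explanation was tested.

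The P450 list was lower in the libraries labelled AFP-positive. A lower share of hepatocyte RNA would lower plasma protein genes alike, and their median did move with that of the P450 list. It was -0.51, -0.61 and 1.02 in pairs 1, 2 and 3, against -0.81, -1.49 and 0.21. The P450 median lay below it in each pair, by -0.298 at the least on the log2 scale. A shared shift can thus be part of the fall, though by itself it would not give the gap between the lists. Background was higher in the libraries labelled AFP-positive in pairs 1 and 2 only, and lower in pair 3. Its subtraction moved the P450 medians to -0.55, -1.17 and -0.18 in pairs 1, 2 and 3. The expected background thus does not account for the whole fall in pairs 1 and 2. The P450 median over all pairs stayed at -0.578 after subtraction, but there background effects of opposite sign offset each other, so it cannot decide alone. A lower share of hepatocyte RNA or more background in pairs 1 and 2 as part of the cause, a lower drug metabolism program in AFP-positive tissue and chance stay open.

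Whether chance gives as many calls could be tested on 10 splits only, too few for a share under 0.05. The real split called 1 gene, and 3 of the 10 splits called as many, with 41 the highest of the others. Of the 10 splits, 6 part 1 pair, and with the block their result rests on the labelled contrast within that pair, which for the 41 genes is pair 2. Of the 4 splits that part all 3 pairs, the real one called 1 gene and the others 0, 0 and 0. For lists the real split called 10, and 6 of 10 splits called as many. The highest of the others was 19, in the split that exchanges the libraries of pair 3, which called 0 genes. Of the other 3 splits that part all 3 pairs, these lists numbered 19, 9 and 4.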
